A study of Mus musculus with 16 samples.

How the data were processed

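The study measured polyadenylated RNA in primary mouse microglia. Per the labels' protocols, cortex and hippocampus of newborn mice were dissociated and grown as mixed glial cultures, and microglia were detached by heated orbital shaking, with no sort or gate named. The cells were WT or Grn knockout and received 2 uM rimeporide or DMSO for 72 h. The labels give 4 libraries in each of 4 groups and describe them as 4 biological replicates per genotype. Read literally, each replicate gave both a DMSO and a rimeporide library. The main fit takes all libraries as independent, so a p-value measures variation between libraries of a group. Whether a DMSO and a rimeporide library with the same number came from the same culture is not given in the sources used here. RNA integrity numbers were 10 in every library but those of KO with rimeporide, which had 10, 9.9, 9.9 and 1 value not given. Libraries were made with a 3' mRNA tag kit with molecular identifiers and read as single ends, per the labels' protocols. Whether the deposited values were counted after removal of duplicates is not given in the sources used here.

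The authors deposited expected counts per gene for 56980 genes, which came from Salmon on the GRCm39 build per the submitters' processing notes. The version of Salmon and the annotation release are not given in the sources used here. The authors also deposited log2 CPM values of the tested genes, whose correlation across genes with log2 CPM computed from the counts was at least 0.9999 in each library. Of the count values 13.7% were not whole, and rounding them for the tests changed 0.0207% of the total. The total count per library ran from 3666367 to 7929470. Gene symbols came from the deposited gene table. Biotypes came from GENCODE M21 by Ensembl identifier, with 115 of the tested genes unmatched, and the order of genes along the chromosome came from the same annotation. That annotation uses another build than the authors did, so no coordinates are given.

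The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12272 genes, of which 10800 were protein-coding and 933 were processed pseudogenes, transcribed ones included. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, which gave 12 residual and 10.8 prior degrees of freedom. There were 7 comparisons: KO against WT in DMSO and in rimeporide, rimeporide against DMSO in WT and in KO, the interaction, the average effect of rimeporide over genotypes, and KO in rimeporide against WT in DMSO. A gene passed with an edgeR p, adjusted by the Benjamini-Hochberg method over the genes of that comparison, under 0.05. Standard errors were derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F. CPM values are given with the SD over 4 libraries.

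Genes were grouped in 32 lists written before the data were examined, on the lysosome and its acidification, lipids, microglial states, immune responses, metabolism, stress, growth and other cell types. Lists with at least 5 tested members were tested with camera of limma 3.58.1, which compares a list with the other genes, at a preset correlation between genes of 0.01, and adjusted over the lists of each comparison. Of the 32 lists 31 had enough members. Each camera call was repeated with a correlation estimated from the data, and fry was run as an alternative. Camera calls that held with the estimated correlation numbered 4 of 17 for KO against WT in DMSO, 8 of 12 in rimeporide and 6 of 12 for KO in rimeporide against WT in DMSO. None held of 5 in the average effect of rimeporide, 5 in WT, 4 in KO and 5 in the interaction. Fry passed 18 lists for KO against WT in DMSO, 16 in rimeporide and 15 for KO in rimeporide against WT in DMSO. It passed 6 in the average effect, 0 in WT, 5 in KO and 0 in the interaction. Among camera calls that fry did not pass were interferon (adjusted p = 0.329), NF-kB (0.0967) and ribosomal protein genes (0.0517) in DMSO. Interferon genes with rimeporide in KO were another (0.315). A list score is the mean of its members' log2 CPM (prior count 2), each centred over the 16 libraries, and scores were compared by exact two-sided permutation tests, stratified by genotype for the average effect. The smallest p that 4 against 4 libraries can give is 0.0286.

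The rule for named genes was fixed before the data were examined. It names Grn always, then the 12 largest increases and the 12 largest decreases among genes that passed, had a mean of at least 5 CPM and carried a gene name, and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p are named and said not to pass. Some genes that the rule selects are not reported here. The examples given for opposite changes, for iron handling and for other lists come from these members. The genes that moved with the processed pseudogenes, and the score of the latter, were examined only after the results were seen.

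The steps were tested on simulated counts drawn with the gene means, dispersions and library sizes of the real samples, with 200 genes changed. For KO against WT in DMSO, 46.3% of the genes changed 1.5-fold were recovered among 12030 tested, 67.7% of those changed 2-fold and 100% of those changed 4-fold. These shares were 40.9%, 73.1% and 95.4% for KO against WT in rimeporide, 43.8%, 71.9% and 93.9% for rimeporide in WT, and 42.2%, 83.6% and 93.5% for rimeporide in KO. They were 26.9%, 47.0% and 88.7% for the interaction, 61.9%, 94.0% and 100% for the average effect, and 36.4%, 61.2% and 98.5% for KO in rimeporide against WT in DMSO. False calls numbered 5 to 14. Genes were drawn independently of each other, so these counts do not cover a property shared by whole libraries. The lysosomal hydrolase list was also raised in the changed groups, and its genes were left out of the false calls.

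Alternatives chosen before the data were examined were RLE scaling, no filter or at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, only the libraries of the comparison, an adjusted p under 0.01, a change of at least 1.5-fold, a block for the replicate number, and the omission of each library in turn. For the opposite changes of genotype and rimeporide, the shared KO libraries with DMSO were also split in pairs. Alternatives chosen after seeing the data were protein-coding genes alone, the processed pseudogene score as a covariate, libraries thinned to the smallest total, and limma-trend on the authors' log2 CPM. For each comparison the count of changed genes was also taken for other splits of the same libraries, 35 for groups of 4 against 4 and 100 drawn splits for the interaction and the average effect. Raw reads were not analysed here.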

Results

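RNA was measured in 16 libraries of primary mouse microglia, made from 4 groups with 4 libraries each. The cells were wild type (WT) or lacked Grn, the gene of progranulin, a secreted protein that reaches lysosomes and is processed there. Each genotype was kept for 72 h with 2 uM rimeporide or with its vehicle DMSO. The libraries hold 3' mRNA tags, and their total counts ran from 3666367 to 5818416 in WT with DMSO, from 4422194 to 7929470 in KO with DMSO, from 4204624 to 5609719 in WT with rimeporide and from 4018800 to 5966708 in KO with rimeporide. The series title names lysosomal acidification in Grn knockout microglia as the subject, so the comparisons ask what the loss of Grn changes, what rimeporide changes in each genotype, and whether rimeporide moves the knockout profile toward WT. Changes are log2 fold changes ± a standard error derived from edgeR's quasi-likelihood F test, with 4 libraries per group. The p-values are adjusted by the Benjamini-Hochberg method unless stated.

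Grn (ENSMUSG00000034708.13) separated the genotypes in every library. Its level was 1729 ± 94.1 CPM (SD, n = 4) in WT with DMSO and 1629 ± 37.0 CPM in WT with rimeporide, against 12.6 ± 1.90 CPM in KO with DMSO and 17.6 ± 4.96 CPM in KO with rimeporide. The lowest WT library stood at 1597 CPM and the highest KO library at 24.2 CPM. Grn was 139-fold lower in KO with DMSO (−7.12 ± 0.14, adjusted p = 3.47e-21) and 90.7-fold lower in KO with rimeporide (−6.50 ± 0.13, adjusted p = 1.63e-20). The deleted part of the gene is not given in the sources used here, so 3' tags that remain in KO do not say whether a transcript or a protein is left.

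In DMSO, the largest increases in KO were transcripts of neurons, astrocytes and oligodendrocyte progenitors. Gap43, a growth cone protein, rose by 6.55 ± 0.64 (adjusted p = 1.11e-07), Ncan, a proteoglycan of the neural matrix, by 5.18 ± 0.26 (adjusted p = 1.94e-12), and Rtn1, a neuronal reticulon, by 4.67 ± 0.21 (adjusted p = 5.11e-13). The adhesion and synapse genes Cntn1 (5.82 ± 0.34), Nrxn2 (4.72 ± 0.28) and Epha5 (4.78 ± 0.47) rose as well. All 6 tested members of the neuron list rose, among them Map2 (3.11 ± 0.31), Tubb3 (2.08 ± 0.24) and Dcx (2.18 ± 0.37), and the count was again 6 adjusted over the list alone (camera adjusted p = 4.53e-11, adjusted p = 0.00539 with an estimated correlation). Of 12 astrocyte genes 8 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.88e-10, adjusted p = 0.0159 with an estimated correlation). Atp1b2 (4.45 ± 0.37), Gfap (4.25 ± 0.36), Slc1a2 (3.81 ± 0.34) and Aldoc (1.70 ± 0.16) were among those that rose. Of 9 oligodendrocyte lineage genes 4 rose, 1 fell and 4 did not pass, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0042, adjusted p = 0.105 with an estimated correlation). The progenitor genes Olig1 (4.46 ± 0.45), Ptprz1 (4.14 ± 0.35) and Olig2 (4.06 ± 0.58) rose. Fibroblast, endothelial and mural genes did not move as a group (2 rose and 4 did not pass, also adjusted over the list alone, camera adjusted p = 0.333), although the endothelial genes Vwf (1.21 ± 0.23) and Flt1 (0.90 ± 0.18) rose. Only 2 lymphocyte, granulocyte and mast cell genes were tested. Kit rose (2.11 ± 0.54, adjusted p = 0.00833) and S100a8 did not pass (adjusted p = 0.985). The neuron genes summed to 9.87 CPM in WT and 63.8 CPM in KO, the astrocyte genes to 127.8 and 179 CPM, and the oligodendrocyte lineage genes to 94.98 and 107.7 CPM. In the plot of marker scores every KO library stood above every WT library.

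**Figure D1:**
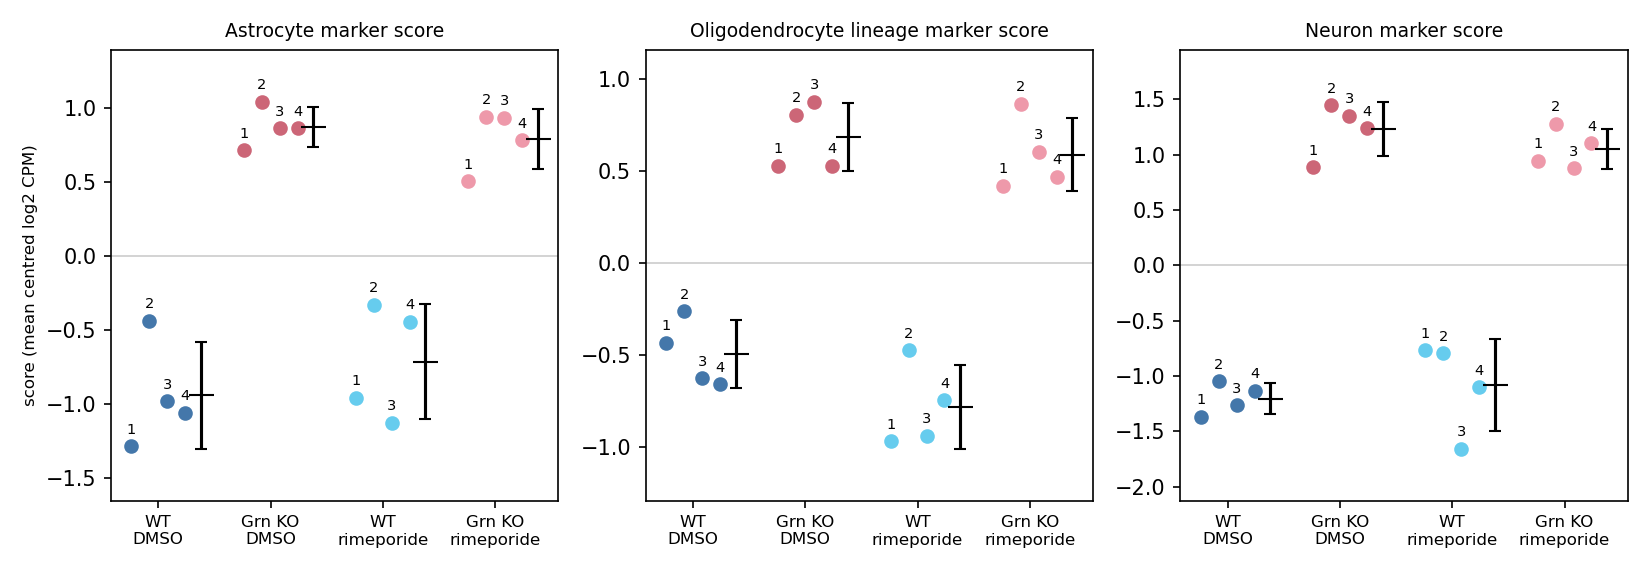
Scores of the astrocyte, oligodendrocyte lineage and neuron lists per library (mean log2 CPM of the tested members, each gene centred over the 16 libraries), with group means. The lowest KO score stands above the highest WT score in each list, and the smallest gap over the 3 lists is 0.682.

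Sterol synthesis genes, which SREBP2 turns on when membrane cholesterol is low, rose next. Of 25 cholesterol biosynthesis and uptake genes 18 rose and none fell, 19 rose adjusted over the list alone, and the list median was 1.93-fold (camera adjusted p = 4.14e-19, adjusted p = 0.00539 with an estimated correlation). Hmgcs1 rose by 1.30 ± 0.10 and Cyp51 by 1.39 ± 0.14. Of 15 LXR target and sterol efflux genes 5 rose, 2 fell and 8 did not pass, and 5 rose and 5 fell adjusted over the list alone. The desaturases Scd2 (2.59 ± 0.14) and Scd1 (2.80 ± 0.42) and Cd5l (1.66 ± 0.14) rose, and Smpdl3a fell (−0.52 ± 0.076). The list passed camera (adjusted p = 0.0165) but not with an estimated correlation (adjusted p = 0.085) nor without WT DMSO replicate 4 (adjusted p = 0.0678). Of 25 lipid droplet and lipid handling genes 12 rose, 5 fell and 8 did not pass, and 12 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00618, adjusted p = 0.0719 with an estimated correlation). The lipase gene Mgll (2.01 ± 0.14), the desaturase Fads2 (2.48 ± 0.24), Acsl3 (1.13 ± 0.10) and the fatty acid carrier Fabp4 (1.08 ± 0.095) rose, and the lipoprotein lipase inhibitor Angptl4 fell (−1.52 ± 0.22).

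Disease-associated microglia genes, the set microglia raise around plaques and damage, rose in KO with DMSO. Of 27 genes 13 rose, 2 fell and 12 did not pass, and 15 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.000108, adjusted p = 0.00539 with an estimated correlation). Mamdc2 (2.20 ± 0.24), the lectin Lgals3 (0.63 ± 0.079) and the receptor Clec7a (0.63 ± 0.085) rose, and the growth factor Igf1 fell (−0.46 ± 0.061, adjusted p = 8.95e-06). Subunits of the V-ATPase, the proton pump that acidifies lysosomes, shifted up: of 18 genes 5 rose and none fell, and 6 rose adjusted over the list alone (camera adjusted p = 0.00842, adjusted p = 0.24 with an estimated correlation, and 0.108 by camera with each library's processed pseudogene score as a covariate). Atp6v0d2 rose by 1.04 ± 0.11 and Atp6v1b2 by 0.48 ± 0.10. Of 50 lysosomal hydrolases and cofactors 8 rose, 3 fell and 39 did not pass, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.164). The protease Ctsz (0.55 ± 0.080), the GM2 activator Gm2a (0.60 ± 0.10) and Naglu (0.59 ± 0.11) rose, and the heparan sulfate acetyltransferase Hgsnat fell (−0.81 ± 0.10). Of 31 lysosomal membrane genes 5 rose and none fell, also adjusted over the list alone, among them Mfsd12 (0.80 ± 0.11) and Cd63 (0.34 ± 0.062), and the list did not pass (camera adjusted p = 0.0545). NRF2 and oxidative stress genes fell. Of 26 genes 7 fell and none rose, 8 fell adjusted over the list alone, and Hmox1 (−0.89 ± 0.13), Taldo1 (−0.66 ± 0.079) and Txnrd1 (−0.62 ± 0.086) were among them (camera adjusted p = 0.000168, adjusted p = 0.085 with an estimated correlation).

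Cell cycle genes also rose in KO with DMSO. Of 42 proliferation genes 17 rose and none fell, 22 rose adjusted over the list alone, with Ccnb1 at 0.94 ± 0.13 and the survivin gene Birc5 at 0.84 ± 0.12 (camera adjusted p = 2.97e-05, adjusted p = 0.171 with an estimated correlation). Of 29 ER chaperone and heat shock genes 8 rose and none fell, also adjusted over the list alone, with Sdf2l1 at 0.79 ± 0.15 and Hsp90b1 at 0.33 ± 0.068 (camera adjusted p = 0.0148, adjusted p = 0.171 with an estimated correlation, and 0.193 by camera with the processed pseudogene score as a covariate). Of 23 ATF4 stress response genes 6 rose, 1 fell and 16 did not pass, and 8 rose and 2 fell adjusted over the list alone, with the serine synthesis gene Phgdh at 1.70 ± 0.23 and the amino acid transporter Slc7a5 at 1.48 ± 0.21. That list passed camera (adjusted p = 0.0306) but not with an estimated correlation (adjusted p = 0.085) nor without WT DMSO replicate 3 or 4 (adjusted p = 0.0508 each) or KO DMSO replicate 2 (adjusted p = 0.0615). Of 23 NF-kB inflammatory genes 9 fell, 3 rose and 11 did not pass, and 11 fell and 4 rose adjusted over the list alone. The prostaglandin synthase gene Ptgs2 fell (−1.66 ± 0.38) and Il1rn rose (0.57 ± 0.13). The NF-kB call (camera adjusted p = 0.0458, adjusted p = 0.469 with an estimated correlation) ended without WT DMSO replicate 4 (0.25), KO DMSO replicate 1 (0.0655), 2 (0.0523) or 3 (0.0594) or WT rimeporide replicate 1 (0.0515). It also ended with the replicate number as a block (0.0624) and with the filter of at least 1 CPM in 4 libraries (0.0542). Of 16 complement and Fc receptor genes 3 fell, 1 rose and 12 did not pass, and 5 fell and 2 rose adjusted over the list alone, with C5ar1 at −0.47 ± 0.071. The complement call (camera adjusted p = 0.0466, adjusted p = 0.267 with an estimated correlation) ended without WT DMSO replicate 1 (0.131) or 4 (0.0759), KO DMSO replicate 2 (0.114) or 4 (0.0727), WT rimeporide replicate 1 (0.0515) or 4 (0.0509) or KO rimeporide replicate 2 (0.0504). It also ended with the replicate number as a block (0.0508) and with no filter on low counts (0.0685). Of 8 border-associated macrophage genes 3 fell and 5 did not pass, and 3 fell and 1 rose adjusted over the list alone, with Folr2 at −0.74 ± 0.096 and Pf4 at −0.59 ± 0.10. The macrophage list passed camera (adjusted p = 0.0231) but not with an estimated correlation (adjusted p = 0.085) nor without WT DMSO replicate 4 (adjusted p = 0.0566).

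Ribosomal protein genes and processed pseudogenes were lower in KO with DMSO. Of 63 ribosomal protein genes 13 fell and none rose, 19 fell adjusted over the list alone, with Rpl10 at −0.71 ± 0.15 and Rpl22 at −0.45 ± 0.099 (camera adjusted p = 8.81e-05, adjusted p = 0.486 with an estimated correlation, and 0.61 by camera with the processed pseudogene score as a covariate). Of 933 processed pseudogenes 349 fell and none rose (median −0.67). Exact permutation tests of the scores gave p = 0.0857 for ribosomal protein genes and 0.0571 for processed pseudogenes. Adjusted over the scores these were 0.125 and 0.0962. Processed pseudogenes can share reads with their parent genes, so their counts are uncertain. Interferon genes had a median of −0.49, and of 37 genes 1 fell, and none adjusted over the list alone (camera adjusted p = 0.00842, adjusted p = 0.665 with an estimated correlation). That call ended without WT DMSO replicate 1 (adjusted p = 0.216) or 4 (adjusted p = 0.0805). Irf7 was the gene that fell (−1.74 ± 0.48, adjusted p = 0.0131), and its call ended without WT DMSO replicate 1 (adjusted p = 0.114) or KO DMSO replicate 1 (adjusted p = 0.0506) or 4 (adjusted p = 0.0529). Of 12272 genes tested, 1236 rose and 1051 fell, and 3911 had an unadjusted p under 0.05. Of the protein-coding genes 1206 rose and 653 fell. With the processed pseudogene score as a covariate, 808 genes passed, 551 higher and 257 lower, and the median absolute change of the 2287 genes went from 0.641 to 0.384. Without KO DMSO replicate 1, the library with the largest total, 1430 genes passed in place of 2287. KO DMSO replicate 2 stood apart from the other 3 KO libraries with DMSO, with a processed pseudogene score of 0.12 against −1.01 to −0.54.

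With rimeporide in both genotypes, neural genes were again higher in KO than in WT. Gap43 (4.72 ± 0.54), Ncan (4.35 ± 0.25), Rtn1 (4.19 ± 0.20, adjusted p = 1.89e-12) and Gpm6b (4.20 ± 0.37) rose. Of the 6 neuron genes 4 rose, of 12 astrocyte genes 7 rose and 1 fell, and of 9 oligodendrocyte lineage genes 5 rose. Adjusted over the list alone, 6 neuron genes rose, 9 astrocyte genes rose and 2 fell, and 5 oligodendrocyte lineage genes rose (camera adjusted p = 1.42e-12, 3.06e-10 and 1.35e-05, and 0.00155, 0.0135 and 0.0135 with an estimated correlation). Map2 (2.95 ± 0.31), Olig1 (5.60 ± 0.56) and Atp1b2 (3.76 ± 0.35) were among them. Of 25 cholesterol genes 15 rose and none fell, 18 rose adjusted over the list alone, with Idi1 at 1.28 ± 0.15 (camera adjusted p = 7.78e-19, adjusted p = 0.00479 with an estimated correlation). Of 15 LXR target genes 5 rose, among them Scd2 (2.39 ± 0.14) and Cd5l (1.33 ± 0.14), and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000126, adjusted p = 0.00912 with an estimated correlation). Of 27 disease-associated microglia genes 7 rose and 1 fell, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.00489 with an estimated correlation). Lgals3 (0.79 ± 0.080), Mamdc2 (2.08 ± 0.24) and Gpnmb (0.59 ± 0.079) rose and Igf1 fell (−0.46 ± 0.061). NRF2 genes fell, 10 of 26, and 12 fell and 1 rose adjusted over the list alone, with Gclc at −0.65 ± 0.10 and Srxn1 at −0.77 ± 0.12 (camera adjusted p = 5.37e-06, adjusted p = 0.0258 with an estimated correlation). Of 8 border-associated macrophage genes 4 fell, also adjusted over the list alone, with Folr2 at −0.73 ± 0.097 (camera adjusted p = 0.00376, adjusted p = 0.0243 with an estimated correlation). The matrix gene Ccn2 (−2.12 ± 0.39) fell, as did the receptor gene Gpr35 (−1.48 ± 0.29).

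Smaller groups differed between the genotypes in rimeporide as well. Of 42 proliferation genes 11 rose and none fell, 17 rose adjusted over the list alone, with Ccna2 at 0.70 ± 0.14 and Prc1 at 0.73 ± 0.14 (camera adjusted p = 8.15e-09, adjusted p = 0.0585 with an estimated correlation). Of 23 immediate early genes 6 fell and 2 rose, and 10 fell and 3 rose adjusted over the list alone, with Klf2 at −0.84 ± 0.19, Dusp1 at −0.57 ± 0.13 and Egr1 at 0.62 ± 0.15 (camera adjusted p = 0.00616, adjusted p = 0.216 with an estimated correlation). Of 10 alternative activation genes 3 fell and 1 rose, and 4 fell and 1 rose adjusted over the list alone, with the scavenger receptor genes Msr1 at −0.52 ± 0.090 and Mrc1 at −0.38 ± 0.090. That list (camera adjusted p = 0.0447, adjusted p = 0.167 with an estimated correlation) no longer passed without WT rimeporide replicate 2 (0.0518) or 4 (0.0753) or KO rimeporide replicate 1 (0.0693) or 4 (0.0593). Of 16 complement genes 6 fell and none rose, and 6 fell and 3 rose adjusted over the list alone, with C1qa at −0.38 ± 0.085 and C5ar1 at −0.43 ± 0.071. The complement call (camera adjusted p = 0.0447, adjusted p = 0.27 with an estimated correlation) ended without WT rimeporide replicate 1 (0.0502) or KO rimeporide replicate 1 (0.0702), 2 (0.0546) or 4 (0.0666). Lysosomal lists did not pass in rimeporide (camera adjusted p = 0.426 for hydrolases, 0.651 for membrane proteins and 0.138 for the V-ATPase), although Psap rose (0.53 ± 0.078) and Hgsnat fell (−1.13 ± 0.11). Plin2, the coat protein of lipid droplets, fell (−0.75 ± 0.070). In all, 631 genes rose and 285 fell, and 2232 had an unadjusted p under 0.05. Whether a gene's genotype difference was larger in one treatment than in the other is the interaction, given with the rimeporide comparisons.

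Knockout cells in rimeporide also differed from WT cells in DMSO. Gap43 (6.35 ± 0.66), Cntn1 (5.52 ± 0.34) and Ncan (4.79 ± 0.26) rose most. Of 25 cholesterol genes 15 rose, of 27 disease-associated microglia genes 10 rose and 1 fell, and of 15 LXR target genes 4 rose and 1 fell. Adjusted over the list alone, these counts were 17 higher for cholesterol, 14 higher and 1 lower for disease-associated genes, and 5 higher and 3 lower for LXR targets (camera adjusted p = 8.95e-17, 2.68e-06 and 0.000977, and 0.00576, 0.00244 and 0.0228 with an estimated correlation). Hmgcs1 (1.11 ± 0.10), Scd2 (2.67 ± 0.14), Lgals3 (0.86 ± 0.080) and Mamdc2 (2.29 ± 0.25) were among them. Of 6 neuron genes 5 rose, of 12 astrocyte genes 8 rose and 1 fell, and of 9 oligodendrocyte lineage genes 4 rose (6, 8 with 2 lower, and 4 with 1 lower adjusted over the list alone, camera adjusted p = 2.18e-12, 2.22e-12 and 0.00273, and 0.00244, 0.00951 and 0.118 with an estimated correlation). NRF2 genes fell (10 of 26 with 1 higher, and 12 with 2 higher adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.0564 with an estimated correlation), and so did border-associated macrophage genes (4 of 8, also adjusted over the list alone, camera adjusted p = 0.00808, adjusted p = 0.0462 with an estimated correlation). Proliferation genes rose (12 of 42, and 15 adjusted over the list alone, camera adjusted p = 2.54e-05, adjusted p = 0.208 with an estimated correlation). Interferon genes were lower, with 17 of 37 past the threshold and 27 adjusted over the list alone, led by Ifit3b (−2.57 ± 0.42, adjusted p = 0.000207), Ifit3 (−2.14 ± 0.41) and the RNA sensor gene Ifih1 (−0.76 ± 0.15). Their camera adjusted p was 5.28e-13, and 0.277 with an estimated correlation. NF-kB genes were lower too, 7 of 23 and 2 higher, 10 lower and 3 higher adjusted over the list alone, with Nfkbia at −0.65 ± 0.13 (camera adjusted p = 0.0134, adjusted p = 0.385 with an estimated correlation, and 0.107 without WT DMSO replicate 4). The nuclear genes of oxidative phosphorylation passed camera upward (adjusted p = 0.0319) with 2 of 61 genes called and none adjusted over the list alone. That call did not hold with an estimated correlation (adjusted p = 0.527) or without WT DMSO replicate 1 (0.0771) or 4 (0.14), WT rimeporide replicate 2 (0.0695) or 3 (0.0641) or KO rimeporide replicate 2 (0.0865) or 3 (0.133). In all, 740 genes rose and 455 fell, with 2626 at an unadjusted p under 0.05. On the authors' log2 CPM, limma-trend called 626 higher and 584 lower, and how those values were scaled between libraries was not tested.

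In WT cells, rimeporide changed no single gene at this threshold. The genes with the smallest p were interferon-induced and did not pass: Ifit3b (−2.31 ± 0.41) and Ifit3 (−2.24 ± 0.41) at an adjusted p of 0.101, and the GTPase genes Irgm2 (−1.06 ± 0.21) and Irgm1 (−1.11 ± 0.23) at 0.15. Adjusted over the list alone, 34 of 37 interferon genes fell, and the list median was 0.512-fold (camera adjusted p = 1.33e-54, adjusted p = 0.0938 with an estimated correlation). The interferon score nevertheless overlapped, since WT DMSO replicate 3 scored −0.37 and the WT libraries with rimeporide scored −0.56 to −0.18, and an exact two-sided permutation test of the score gave p = 0.0571, where 0.0286 is the smallest p that 4 against 4 libraries allow. Antigen presentation genes were lower, with 8 of 17 lower adjusted over the list alone, among them Tap1 (−0.69 ± 0.21), Cd86 (−0.58 ± 0.18) and H2-Q7 (−1.39 ± 0.45), none past the threshold over all genes (camera adjusted p = 2.17e-08, adjusted p = 0.209 with an estimated correlation). Mitochondrially encoded genes were higher as a list (median 0.17, camera adjusted p = 6.63e-06, adjusted p = 0.286 with an estimated correlation), with mt-Nd3 at 0.39 ± 0.13. Ribosomal protein genes and nuclear oxidative phosphorylation genes were slightly higher (median 0.073 and 0.069, camera adjusted p = 8.91e-05 and 0.00441, adjusted p = 0.566 each with an estimated correlation), and no member of these 3 lists passed, over all genes or adjusted over the list alone. The oxidative phosphorylation call ended without WT DMSO replicate 4 (0.16) or WT rimeporide replicate 3 (0.0931), and the ribosomal call without the same libraries (0.121 and 0.176). Beside the count of 0 from edgeR, 676 genes had an unadjusted p under 0.05, DESeq2 called 6 genes and limma-voom 0. With the replicate number as a block, edgeR called 8 genes. Leaving out WT DMSO replicate 3 gave 40 genes and leaving out KO DMSO replicate 2 gave 12.

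**Figure D2:**
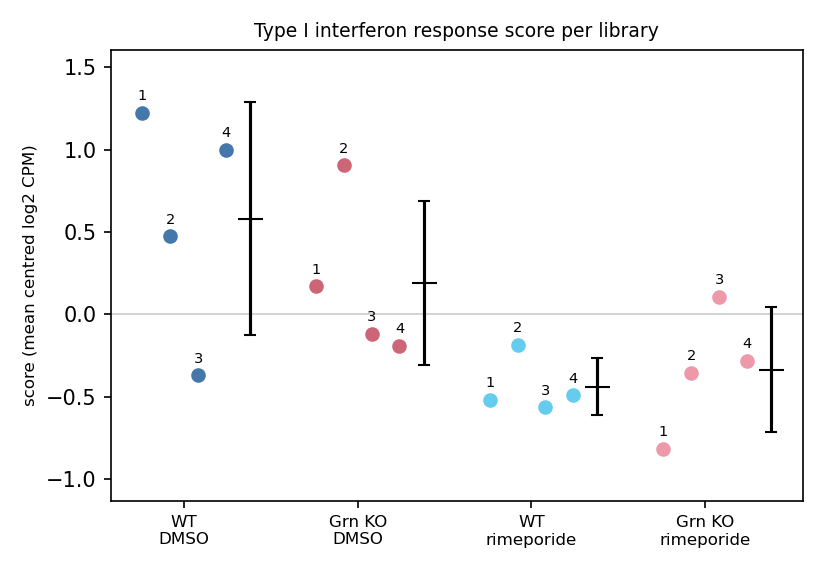
Score of the type I interferon list per library (mean log2 CPM of the 37 tested members, each gene centred over the 16 libraries), with group means. WT DMSO replicates 1 and 4 score 1.22 and 0.998, WT DMSO replicate 3 scores −0.37, and KO DMSO replicate 2 scores 0.90 while the other KO libraries with DMSO score −0.19 to 0.17.

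In KO cells, ribosomal protein genes and the processed pseudogenes were higher with rimeporide, and interferon and lysosomal membrane genes were lower. Of 63 ribosomal protein genes 26 rose and none fell, and 33 rose and 2 fell adjusted over the list alone, with Rpl22 at 0.52 ± 0.099 (camera adjusted p = 2.68e-09, adjusted p = 0.703 with an estimated correlation). Of 933 processed pseudogenes 504 rose and 1 fell, with a median of 0.92, and the 12 largest increases among genes with a name included Rps2-ps8 (1.78 ± 0.32) and Rpl30-ps3 (1.65 ± 0.30), whose reads can be shared with their parents and whose values are uncertain. Of 61 nuclear oxidative phosphorylation genes 14 rose and 1 fell, and 16 rose and 3 fell adjusted over the list alone, with Ndufs1 at 0.41 ± 0.085 and the ATP synthase gene Atp5b at 0.44 ± 0.093. That list (camera adjusted p = 0.0286, adjusted p = 0.711 with an estimated correlation) no longer passed without KO DMSO replicate 2 (0.125) or 4 (0.089) or KO rimeporide replicate 2 (0.063) or 3 (0.0873). Of 31 lysosomal membrane genes 6 fell and none rose, and 7 fell adjusted over the list alone, with Laptm4a at −0.55 ± 0.10 and Scarb2, which carries glucocerebrosidase to lysosomes, at −0.49 ± 0.099. The lysosomal call (camera adjusted p = 0.0286, adjusted p = 0.689 with an estimated correlation) ended without KO DMSO replicate 2 (0.0602) or KO rimeporide replicate 3 (0.0873). Atp6v1b2 (−0.51 ± 0.10) and the autophagy kinase gene Ulk1 (−0.98 ± 0.18) fell, as did Hexa (−0.40 ± 0.080), while the V-ATPase list did not pass (camera adjusted p = 0.054). Of 37 interferon genes 6 fell, and 7 adjusted over the list alone, among them Slfn5 (−0.85 ± 0.17, adjusted p = 0.00396) and Ifit3b (−1.77 ± 0.43, adjusted p = 0.00955). The interferon list passed camera (adjusted p = 7.6e-05) but not with an estimated correlation (adjusted p = 0.711) nor without KO DMSO replicate 2 (adjusted p = 0.105). The lipid genes Hilpda (−0.78 ± 0.14) and Fabp3 (−0.74 ± 0.14) fell, Lilrb4a (0.90 ± 0.16) rose, and Jun (−0.43 ± 0.098) and Fosl2 (−0.54 ± 0.11) fell. Grn itself rose by 0.53 ± 0.15 (adjusted p = 0.019) from its low KO level, a call that ended without KO DMSO replicate 1 (0.0847) or 4 (0.0588) or KO rimeporide replicate 3 (0.181).

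The count of changed genes in KO cells depended on single libraries. Of 12272 genes 1034 rose and 779 fell, and of the protein-coding genes 497 rose and 764 fell, with 3553 genes at an unadjusted p under 0.05. The count of 1813 became 751 without KO DMSO replicate 1, 3002 without KO DMSO replicate 2, 643 without KO DMSO replicate 4, 1195 without KO rimeporide replicate 2 and 754 without KO rimeporide replicate 3. On the authors' log2 CPM, limma-trend called 746 higher and 1301 lower. There the median of all genes was −0.106 in place of −0.0081, the ribosomal median was 0.12, and the oxidative phosphorylation median was 0.002 with 5 genes higher and 5 lower. Both list medians still lay above the median of all genes. The processed pseudogene score was −0.55 ± 0.48 (SD, n = 4) in KO with DMSO, 0.316 ± 0.205 in KO with rimeporide, 0.114 ± 0.185 in WT with DMSO and 0.12 ± 0.28 in WT with rimeporide. Between the KO groups an exact permutation test of it gave p = 0.0286, and 0.153 adjusted over the scores. The changed genes moved with this score: with it as a covariate, 1 gene passed in KO cells.

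**Figure D3:**
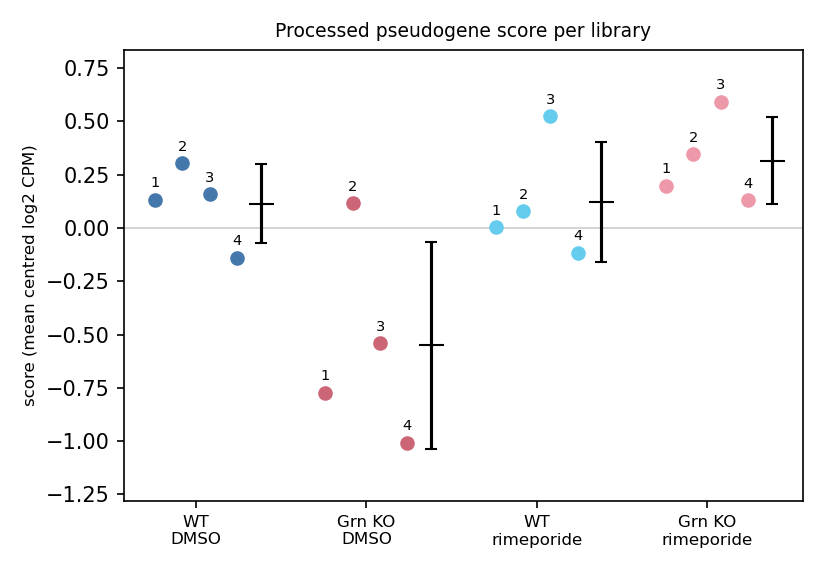
Processed pseudogene score per library (mean log2 CPM of the tested processed pseudogenes, each gene centred over the 16 libraries), with group means. KO DMSO replicates 1, 3 and 4 score −0.77, −0.54 and −1.01, KO DMSO replicate 2 scores 0.12, and the KO libraries with rimeporide score 0.13 to 0.59.

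Of the 2287 genes that differed between KO and WT in DMSO, 831 passed in the opposite direction with rimeporide in KO cells and 5 in the same direction. Of these 831 genes 502 were protein-coding and 308 were processed pseudogenes. Examples are Rpl10 and Rpl22, lower in KO and higher with rimeporide, and Atp6v1b2 and Mfsd12, higher in KO and lower with rimeporide. Both comparisons use the same 4 KO libraries with DMSO, which creates opposite changes with no effect of rimeporide at all: 20 simulated data sets without any effect gave a correlation across genes of −0.467 on average (−0.489 to −0.449), against −0.455 observed. The observed covariance was −0.138 and the simulated one −0.0284, a difference of −0.109. Independent lists of these sizes would share 167 genes in opposite directions. When the 4 libraries were split into pairs, each comparison with its own pair, the 6 ways of splitting gave 0 to 155 genes in opposite directions, with a mean of 74.7 and with 6.67 in the same direction, where independent lists would share 31.8. With no library shared in these 6 splits, the correlation was negative in each, from −0.455 to −0.17 with a mean of −0.323, and the mean covariance was −0.108. A property common to the KO libraries with DMSO stays in both pairs, and genes were simulated independently of each other. Neither the splits nor the simulation can therefore tell such a property from an effect of rimeporide. With the processed pseudogene score as a covariate, 1 gene changed in opposite directions. The count was 277 without KO DMSO replicate 1, 1791 without replicate 2, 543 without replicate 3 and 249 without replicate 4 of the same group, 468 without KO rimeporide replicate 3 and 515 without WT DMSO replicate 2. The KO profile in rimeporide, measured against WT in DMSO without these shared libraries, is given with that comparison.

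The interaction asks whether rimeporide acted differently in the genotypes, and edgeR called 2 genes. Ncaph2, a condensin subunit gene, and Fbxo34, an F-box gene, had a larger change in KO than in WT by 0.98 ± 0.17 and 0.94 ± 0.16 (adjusted p = 0.0368 each). Ncaph2 lost its call in 11 of the 16 omissions of a library and Fbxo34 in 12, so neither is firm. Nfatc1 (0.87 ± 0.17) and Dynlt1f (0.95 ± 0.18) followed without passing (adjusted p = 0.0952 each). Grn did not pass (0.62 ± 0.18, adjusted p = 0.0976). By camera, interferon genes (median 0.54, adjusted p = 0.0039) and ribosomal protein genes (median 0.11, adjusted p = 0.0039) were higher in the interaction, and mitochondrially encoded genes (median −0.28, adjusted p = 0.00472), ER chaperones (median −0.14, adjusted p = 0.016) and immediate early genes (median −0.26, adjusted p = 0.016) were lower. All 5 had an adjusted p of 0.602 with an estimated correlation, and no member passed over all genes. Adjusted over the list alone, 5 mitochondrially encoded genes were lower, 2 ER chaperone genes lower, 1 immediate early gene lower, 1 ribosomal protein gene higher and no interferon gene. The interferon call ended without WT DMSO replicate 1 (0.265) or 4 (0.0759) or KO rimeporide replicate 3 (0.063), and the mitochondrial call without WT DMSO replicate 4 (0.0742) or KO rimeporide replicate 3 (0.0592). The chaperone call ended without WT DMSO replicate 1 (0.0636) or KO rimeporide replicate 3 (0.063), the immediate early call without the same libraries (0.0636 and 0.0592), and the ribosomal call without KO DMSO replicate 4 (0.109) or KO rimeporide replicate 3 (0.063). At an unadjusted p under 0.05 there were 2277 genes. With the replicate number as a block edgeR called 690, and whether the numbers mark pairs is not known. DESeq2 called 276 genes and limma-voom 166. The count was 1497 without KO DMSO replicate 2, 253 without WT rimeporide replicate 3, 5 without WT DMSO replicate 4, 2 without WT rimeporide replicate 1, 1 without KO rimeporide replicate 1 and 0 in the other 11 omissions.

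Averaged over the genotypes, interferon genes were lower with rimeporide. Ifit3b (−2.04 ± 0.30, adjusted p = 0.00652), Ifit3 (−1.82 ± 0.29), Ifit2 (−1.57 ± 0.28), the ubiquitin-like modifier gene Isg15 (−1.34 ± 0.23) and Slfn5 (−0.72 ± 0.12) fell and passed in all 16 omissions of a library. Other calls held less well: of the 25 genes that passed here and were followed through the omissions 20 lost their call in at least 1 omission, among them the interferon genes Ifit1, Oas3, Rsad2, Cmpk2, Ifi209 and Iigp1. Of 37 interferon genes 15 fell, 32 adjusted over the list alone, and none rose (camera adjusted p = 2.96e-27, adjusted p = 0.429 with an estimated correlation). An exact stratified permutation test of the interferon score, over 4900 labellings within the genotypes, gave p = 0.00898, and 0.0958 adjusted over 32 scores. Antigen presentation genes were lower (2 of 17, and 4 adjusted over the list alone, camera adjusted p = 0.00238, adjusted p = 0.491 with an estimated correlation), a call that ended without KO DMSO replicate 2 (0.0616). Lysosomal membrane genes were lower (3 of 31, and 6 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.429 with an estimated correlation, and 0.0524 by camera with the pseudogene score as a covariate). Ribosomal protein genes (10 of 63, and 30 adjusted over the list alone) and nuclear oxidative phosphorylation genes (5 of 61, and 8 adjusted over the list alone) were higher (camera adjusted p = 1.21e-12 and 0.000636, adjusted p = 0.491 each with an estimated correlation). In all, 249 genes rose and 200 fell, and 2711 had an unadjusted p under 0.05. With the replicate number as a block, 1275 genes passed. Limma-trend on the authors' log2 CPM called 142 higher and 297 lower, and with the processed pseudogene score as a covariate 17 genes were lower and none higher. The count of 449 became 11 without WT DMSO replicate 4, 12 without KO DMSO replicate 1, 1746 without KO DMSO replicate 2, 51 without KO DMSO replicate 4, 296 without WT rimeporide replicate 1, 73 without WT rimeporide replicate 2, 15 without WT rimeporide replicate 3, 736 without WT rimeporide replicate 4, 293 without KO rimeporide replicate 1, 15 without KO rimeporide replicate 2 and 50 without KO rimeporide replicate 3.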

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

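The tests of depth, shared reads, carried-over cells and interferon genes in this part were chosen only after the results were seen, the test of the WT slope was chosen after the pseudogene pattern was seen but before its own result, and the counts for other splits were set before. In each group of 4 libraries, 33 scores and totals and 173 genes were searched for a library whose gap to its nearest neighbour, as a ratio to the group's range, was over the 5% critical value of Dixon's test for 4 values. Chance alone gives this in about 1 of 20 groups. Of 824 groups 49 had such a library, 8 of them among scores and totals. The total is close to that chance rate, so a single entry is weak. A high ratio can also be a small gap: Cytip stood at 16.9 CPM in KO DMSO replicate 4, against 18.65 to 18.95 CPM in the rest of that group.

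KO DMSO replicate 2 stood apart most often. It had the lowest score of lysosomal hydrolases (ratio 0.902), and its CPM stood apart for Lrig1 (0.976, 63.0 CPM against 4.98 to 6.37), Isg15 (0.836), Ccl5 (0.86), H2-Q7 (0.837), Cx3cr1 (0.843), Slc11a2 (0.878), and the pseudogenes Rps10-ps1 (0.928), Rps2-ps8 (0.897) and Rpl9-ps7 (0.843). KO DMSO replicate 4 stood apart for Cytip (0.857) and Smpdl3a (0.859). Among KO libraries with rimeporide, replicate 3 had the largest total (0.944), replicate 1 stood apart for Enpp4 (0.915), replicate 2 for the LXR target score (0.843), Tmod2 (0.855) and Scarna2 (0.867), and replicate 4 for the NF-kB score (0.898), Sncaip (0.921), Ccl5 (0.845) and Rpl10 (0.831). Among WT libraries with DMSO, replicate 1 stood apart for Ncoa4 (0.961), replicate 2 for Gpm6b (0.924), Ccn2 (0.842), Ctsz (0.856), Sdf2l1 (0.9) and Tubb3 (0.933), replicate 3 for the ATF4 score (0.9) and Tap1 (0.859), and replicate 4 for Olig1 (0.883), Nfkbia (0.853) and Rpl31-ps13 (0.86). WT rimeporide replicate 4 stood apart for the ATF4 score (0.849), the NRF2 score (0.838), Slc11a2 (0.988), Flt1 (0.94), Slc7a5 (0.89), Birc5 (0.858), Cntn1 (0.847) and Cx3cr1 (0.832). In the same group, replicate 1 stood apart for the lysosomal membrane score (0.937), Col11a1 (0.869), Dusp1 (0.856) and Tnc (0.847), replicate 2 for Map2 (0.983) and Pf4 (0.955), and replicate 3 for Rpl29-ps2 (0.914), Rps10-ps1 (0.873) and Atp1b2 (0.862).

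The interaction passed for Ncaph2 (log2 difference 0.98) and Fbxo34 (0.94) by edgeR, neither of them firm, and for 5 lists by camera. The adjusted p was 0.0039 for interferon genes and for ribosomal protein genes, 0.00472 for mitochondrially encoded genes, and 0.016 for ER chaperones and for immediate early genes. None of the 5 lists held with an estimated correlation (adjusted p = 0.602 each), and each ended without KO rimeporide replicate 3, with adjusted p of 0.0592 to 0.063.

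Other splits of the same libraries show how often a count of genes as high as the real one arises. Only the real split did so for KO against WT in DMSO (1 of 35 splits, with 2287 genes, and 1590 in the highest other). The same held in rimeporide (1 of 35, 916 and 0) and for KO in rimeporide against WT in DMSO (1 of 35, 1195 and 0). It also held for rimeporide in KO (1 of 35, 1813 and 1579), while the average effect had 2 of 100 (449 and 1606). The smallest share that 35 splits can give is 1 of 35, and the shares were not adjusted over the comparisons. Chance is thus made less likely for these counts but is not excluded. The split with 1606 genes, and the next one with 109, keep the KO libraries in their real groups with the direction turned and mix only WT, so they still hold the contrast within KO. With the replicate number as a block 690 genes passed in the interaction, and other splits were not counted with the block. Chance cannot be excluded for the 2 genes of the interaction called without it, since 6 of 100 splits gave as many. The highest other split there gave 1061 genes, many times the real count, which points to a structure of the samples: that split and those with 1590 and 1579 genes part KO DMSO replicate 2 from the other 3 KO libraries with DMSO. In WT alone edgeR called 0 genes, so 35 of 35 splits gave as many by necessity and the splits decide nothing there (23 in the highest other). Beside that 0 stood 676 genes at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom.

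The first pattern is the 1813 genes changed between rimeporide and DMSO in KO cells, with processed pseudogenes higher as a class (median 0.918, which is 0.949 above protein-coding genes of matched abundance). The number of counts alone is argued against, since 1543 genes passed with every library thinned to the smallest total. Thinning cannot undo a shift that a deeper library already held, so a property that goes with depth stays open. KO DMSO replicates 1, 3 and 4 had the largest totals of the 16 libraries (7929470, 6659395 and 6660529). They also had the lowest pseudogene scores (−0.773, −0.541 and −1.008), while KO DMSO replicate 2 had a total of 4422194 and a score of 0.116. Reads passed from parent genes to pseudogenes are argued against for most of the CPM that the called protein-coding genes lost. Those that fell lost 31450 CPM while the processed pseudogenes gained 6959 CPM, and the protein-coding genes that rose gained 36250 CPM at the same time. These sums do not say for how many of the genes this holds. A constant share of parent reads is argued against for the 237 pseudogenes named after a tested parent, whose change exceeded the parent's by a median of 0.705 (quartiles 0.496 and 0.957), while a share that differs between libraries was not tested. A library property other than rimeporide stays open, and not for this comparison alone: across protein-coding genes, which are not independent replicates, the slope on the pseudogene score within WT groups correlated with the change in KO (Spearman rho 0.408) and with KO against WT in DMSO (Spearman rho −0.285). The Spearman rho was 0.071 for KO against WT in rimeporide and 0.106 for KO in rimeporide against WT in DMSO. With that score as a covariate the median absolute change of the called genes fell from 0.573 to 0.133 (median standard error 0.145 and 0.172) in KO and from 0.641 to 0.384 (0.16 and 0.172) between the genotypes in DMSO, so calls ended because the change shrank, and since the score differs between the KO groups a true effect of rimeporide or of Grn loss may have been removed with it.

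The second pattern is the neural transcripts and the cholesterol genes higher in KO. Cells of every other type carried over alike are argued against, because the astrocyte median change in DMSO exceeded that of fibroblast, endothelial and mural genes by 2.195, and the difference of the 2 scores between genotypes over both treatments had an exact stratified permutation p = 0.000408. Astrocyte-like, progenitor-like or neuron-like cells carried over more often in KO cultures remain a candidate source, since the labels name no sort that would remove them. The KO and WT scores were apart by at least 0.682 in all 3 lists. A change in gene expression of KO microglia would set the scores apart as well, so it was not separated from carried-over cells. The most abundant markers in KO were Cxcl14 (77.2 CPM, and 106 in WT), Mbp (37.5, and 47.1 in WT) and Map2 (22.0, and 2.37 in WT), and WT libraries also held 2 of 12 astrocyte, 3 of 9 oligodendrocyte and 0 of 6 neuron genes at 5 CPM or more, with 1 astrocyte gene, Aldoc, in another list. The neural lists gained 117.8 CPM and the cholesterol list 640.7 CPM, but what such cells bring in sterol genes was not measured, so carried-over cells and an effect of Grn loss both stay open for the cholesterol genes. The same question was not tested for the other lists that were higher in KO, such as the LXR, lipid handling, ATF4 and proliferation genes.

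The third pattern is the lower interferon genes with rimeporide. Chance differences in the interferon state of cultures stay open: the exact stratified permutation p of the score was 0.00898, but 0.0958 adjusted over 32 scores, and the genotypes alone gave 0.0571 in WT and 0.143 in KO. The property that moves the pseudogenes is argued against as the whole cause, since 11 of the 15 interferon genes called in the average effect were still called with the score as a covariate. An effect of rimeporide on interferon genes may be real, as a hypothesis found and tested on the same data.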

How the results depend on the processing

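Of the alternatives, protein-coding genes alone, the pseudogene score as a covariate, thinning and limma-trend on the authors' log2 CPM were chosen after seeing the data. Over 10 counts, 193 of 270 alternative values were within 1.5 times the main one. Direction and side of the threshold were kept in 6309 of 6716 values for 251 named genes, with 349 no longer past it, 49 newly past it and 9 of the other sign, and in 1243 of 1380 values for 60 list calls. No call of the 7 comparisons changed sign on the authors' log2 CPM. RLE scaling moved no count by over 1.5 times. Except where stated, the cause of a difference was not tested.

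With no filter on low counts, more genes were tested and 95 passed for rimeporide in WT, 630 for the interaction (377 higher, 253 lower), 970 for the average effect, and 96 list calls in place of 60. DESeq2 called 6, 276 (146 higher, 130 lower) and 801 in the same comparisons, and limma-voom 0, 166 (143 higher, 23 lower) and 746 (494 higher, 252 lower). An adjusted p under 0.01, stricter by construction, left 1145 genes for KO against WT in DMSO, 554 in rimeporide, 599 for rimeporide in KO, 0 for the interaction, 7 for the average effect, 667 for KO in rimeporide against WT in DMSO and 215 genes with opposite changes. A change of at least 1.5-fold left 1276 in DMSO, 872 for rimeporide in KO (651 higher, 221 lower), 136 for the average effect (103 higher, 33 lower), 747 for KO in rimeporide against WT in DMSO and 397 opposite changes. With only protein-coding genes, 1106 passed for rimeporide in KO and 474 changed in opposite directions. Of 60 list calls 18 held with an estimated correlation. With no filter, camera calls also ended for alternative activation genes in rimeporide (0.114) and for oxidative phosphorylation with rimeporide in KO (0.0688). With at least 1 CPM in 4 libraries, the oxidative phosphorylation call in KO with rimeporide against WT in DMSO ended (0.071). With the KO libraries split in pairs, the mean of opposite changes was 74.667, from fewer libraries. Thinning left 1 gene in the interaction and limma-trend 0.

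With the pseudogene score as a covariate, 808 genes passed for KO against WT in DMSO (551 higher, 257 lower), 2 for rimeporide in WT, 1 in KO, 0 for the interaction, 17 for the average effect (0 higher, 17 lower), and 1 gene changed in opposite directions. Of the calls of the main test 349 of 1813 for rimeporide in KO and 45 of 2287 for KO against WT in DMSO had the other sign with this covariate. Among the results named here, signs turned for Adm (0.021) with rimeporide in KO, and for ribosomal protein genes in the interaction (camera adjusted p = 0.101). Camera calls also ended for the V-ATPase (0.108), interferon (0.482), ER chaperones (0.193) and ribosomal proteins (0.61) in DMSO, for lysosomal membrane (0.205), oxidative phosphorylation (0.833) and ribosomal proteins (0.927) with rimeporide in KO, for interferon (0.793), mitochondrially encoded genes (0.429), ER chaperones (0.429) and immediate early genes (0.511) in the interaction, for lysosomal membrane (0.0524) in the average effect and for oxidative phosphorylation (0.0631) in KO with rimeporide against WT in DMSO.

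The replicate numbers were not taken as pairs in the main fit, since the labels do not say which libraries share a culture. Deviations of libraries with the same number correlated from −0.045 to 0.325 between treatments in WT and from 0.031 to 0.268 in KO. In each genotype 5 of 8 libraries correlated best with their own number. Between genotypes 4 of 8 did in DMSO, 6 of 8 in rimeporide and 3 of 8 across both factors, where chance gives about 2 of 8. This is a hint from the data. The labels' 4 biological replicates per genotype point to shared replicates within a genotype, but do not say that the numbers mark them. With the replicate number as a block, 2936 genes passed for KO against WT in DMSO, 1104 in rimeporide, 8 for rimeporide in WT, 2355 in KO, 690 for the interaction, 1275 for the average effect, 1493 for KO in rimeporide against WT in DMSO, and 1298 changed in opposite directions. With the block, list calls numbered 67, and S100a8 had 0.056 in KO against WT in DMSO. If the numbers mark pairs, the main fit ignored that pairing, and so did the permutation tests of scores.

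A value near 0 that never passed changed sign. S100a8 in KO against WT in DMSO gave 0.022 with no filter, 0.162 by limma-voom, 0.132 by limma-trend and −0.303 to 0.23 without 1 library.

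Leaving out 1 library gave ranges of 1430 to 3345 genes for KO against WT in DMSO, 701 to 1086 in rimeporide, 0 to 40 for rimeporide in WT, 643 to 3002 in KO, 0 to 1497 for the interaction, 11 to 1746 for the average effect, 912 to 1441 for KO in rimeporide against WT in DMSO, 249 to 1791 for opposite changes and 53 to 69 for list calls. The lowest values came without KO DMSO replicate 1 in DMSO (1430) and without KO DMSO replicate 4 in KO (643) and for opposite changes (249), and the highest of these 3 without KO DMSO replicate 2 (3345, 3002 and 1791). Without the same replicate the interaction (1497) and the average effect (1746) were also highest. Other libraries moved these 2 counts as well: the average effect was 11 without WT DMSO replicate 4, 12 without KO DMSO replicate 1, and 15 without WT rimeporide replicate 3 or without KO rimeporide replicate 2, and the interaction was 253 without WT rimeporide replicate 3. Grn in DMSO ranged from −7.218 to −7.043. With the depth, dispersion and number of libraries at hand, 26.9% to 61.9% of simulated 1.5-fold changes were recovered, and these 3 limits were not separated. Depth alone was varied by thinning, which gave 1952 genes in place of 2287 for KO against WT in DMSO and 1543 in place of 1813 for rimeporide in KO.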

Other observations

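The neighbour test was written before its result was seen, and the list results are those of the planned tests. Several gene groups held single changes in KO with DMSO without moving as a list. Homeostatic microglia genes did not pass (camera adjusted p = 0.661), although the matrix gene Sparc (−1.17 ± 0.24) and the fractalkine receptor gene Cx3cr1 (−0.61 ± 0.16) fell and the lipid receptor gene Gpr34 (0.74 ± 0.17) rose among 3 higher and 2 lower of 22. Iron handling did not pass (camera adjusted p = 0.379), with 3 higher and 2 lower of 15: the transporter gene Slc11a1 of late endosomes fell (−0.81 ± 0.11), and Slc11a2 (0.62 ± 0.12) and the ferritin receptor gene Ncoa4 (0.35 ± 0.070) rose. Of 27 TFEB and autophagy genes 2 rose and 1 fell, with Fnip2 (0.44 ± 0.094) and Ulk1 (0.65 ± 0.17) higher and the autophagy receptor gene Sqstm1 (−0.41 ± 0.074) lower (camera adjusted p = 0.875). Ulk1 fell with rimeporide in KO (−0.98 ± 0.18), but its call in DMSO ended without KO DMSO replicate 1 (adjusted p = 0.0604) or 4 (adjusted p = 0.0576). Of 15 sodium-proton exchangers and pH regulators 2 rose, led by the pump subunit gene Atp1b1 (4.20 ± 0.28), which neurons and astrocytes also express (camera adjusted p = 0.0703). Of 30 glycolysis and hypoxia genes 3 rose and 3 fell, with Pgam1 (0.51 ± 0.089) higher and Mxi1 (−0.59 ± 0.12) lower (camera adjusted p = 0.623). The class II chaperone gene H2-DMb1 (0.87 ± 0.18) was the 1 antigen presentation gene that rose, the transcription factor genes Egr1 (0.86 ± 0.145) and Egr2 (1.66 ± 0.29) rose while Fos fell (−0.60 ± 0.15), and none of 5 sex genes changed (camera adjusted p = 0.731). The kinase gene Dmpk (−2.40 ± 0.30), the synphilin gene Sncaip (−1.67 ± 0.23) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (−1.56 ± 0.31) were the protein-coding genes outside the lists that fell most after Grn.

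Knockout alleles can carry variants of the strain they were made in, so genes beside Grn may differ for that reason. Of the 100 tested genes nearest to Grn in gene order, 21 were called in KO against WT in DMSO (exact 95% interval of the share 13.5% to 30.3%), against 18.5% of 12056 other genes (one-sided Fisher exact p = 0.302). For genes called in both treatments the shares were 7% and 5.13% (one-sided Fisher exact p = 0.255). Among the 21 were Gfap (4.246) of the astrocyte list and Naglu (0.594) of the hydrolase list. The share can thus hold changes of another origin than such variants. Within 2 places of Grn, Fam171a2 (2.133, adjusted p = 0.00137) and Rundc3a (1.837, 0.00993) passed in DMSO, while Slc25a39 (0.44) and Gpatch8 (0.871) did not. In rimeporide Rundc3a (2.633, adjusted p = 0.0115) and Slc25a39 (0.455, 0.00606) passed, while Fam171a2 (0.0969) and Gpatch8 (0.305) did not. A share over 100 genes can miss an effect limited to the nearest ones. An excess is not shown, and the hypothesis stays open because the interval reaches 30.3%, so the bound written beforehand for excluding it was not taken as met.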
